A study of Caenorhabditis elegans and Homo sapiens with 66 samples.

How the data were processed

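The samples were ribosome footprints of FLAG-tagged GCN-1 worms and of HEK293T cells with and without a GCN1 pull-down, footprints and mRNA of worm strains, and a 4-thiouridine chase of HEK293T cells (66 samples in 29 groups). Per the labels' protocols, lysates for the worm pull-down were partially digested with RNase I at 4 °C for 1 h, worms were kept at 20 °C unless otherwise stated, those for strain footprints with 200 µM FUdR from the L4 or young adult stage, and chase cells had 100 µM 4-thiouridine for 24 h before 0, 2, 4 or 8 h of chase. The G418 concentration is given as 20 µg/ml in one passage of the labels and in another unit in a second. The deposited count tables hold whole-number counts per gene and library, made by the authors. Per the submitters' processing notes the tools were UMI-tools, Bowtie2 2.4.2, STAR 2.7.10a and DESeq2, without role or order, on builds hg38, WBcel235 and ce11. The read counter and its filters are not given in the sources used here. The half-life tables, 1 per genotype as deposited, hold a CPM column (counts per 1000000 over the listed genes, scaled by the authors) and a score column, taken as the half-life that the authors fitted because the tables are named so. The score has no stated unit and the way it was fitted is not given. Of 19099 genes listed, 1342 in WT and 2239 in GCN1 had a negative score and 3357 and 3453 a repeated default without R squared. These were left out.

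The 42 count libraries had totals of 653142 to 55511837, and 41 entered the fits. Replicate A of the treated HEK293T input was left out, because its deposited values of 1000 or more had lost digits: the median ratio to replicate B was 0.675 for genes of 500 to 1000 counts in B and 0.0706 for 1000 to 10000, with lower ratios above, and no value exceeded 999. Replicates within a group had Spearman correlations of 0.953 to 0.998 over genes with 100 counts or more. Worm identifiers were read against Ensembl release 115 (WBcel235), which held 46817 of 46904. No human annotation was at hand, so human genes stay as identifiers and 21 human gene lists were not tested.

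Each of 21 comparisons used the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on counts with TMM factors, genes kept by filterByExpr and a Benjamini-Hochberg threshold of 0.05. Differences of effects were interaction terms in one model. Standard errors of log2 fold changes come from the quasi-likelihood statistic. 25 worm gene lists were tested by camera on log2 CPM (prior count 2, preset correlation 0.01, lists of 5 tested members or more), with an estimated correlation as the alternative, and lists from the monosome IP in nc40 and YFP comparisons. A gene with a group at 0 got a bound against a floor of 3 counts over the group. Named genes were gcn-1 and the YFP reporter, the 6 highest and 6 lowest fold changes (3 and 3 in interactions and in the FLAG strain) past the threshold with a mean log2 CPM of 4 or more, replicates that did not overlap (not asked of interactions) and a gene symbol, and the 3 members of smallest p in each list past the threshold. HEK293T genes lack symbols, so 2 identifiers per side were named there, a number set after the data were examined. Lists, tests and this rule were written before the data were examined, as were all alternatives but those with replicate A of the treated input or limited to its genes under 500 counts. The alternatives were RLE factors, the DESeq2 Wald test (version 1.42.0), no filter beyond 1 count, the replicate as a block and each library left out, with 3 other selections of half-lives.

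Half-lives were compared as log2 ratios per gene with no test. Lists from the untreated HEK293T IP were set against 10000 random lists matched over 20 bins of half-life, and the binomial interval is exact (Clopper-Pearson). The labels give replicates A and B in each group, and the A minus B differences of the paired groups had correlations of -0.0134 to 0.213 across genes, so the main fits were unpaired. Figures were drawn with matplotlib 3.10.9.

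The tests were tried on simulated data with 200 changed genes, 50 at each of 1.5, 2, 4 and 8-fold, at the depth and spread of each comparison. In that order the shares recovered were 42, 36, 86 and 90% in the worm monosome IP, 16, 42, 80 and 86% in the disome IP, 16, 34, 44 and 74% in disome against monosome enrichment, 56, 78, 94 and 92% in occupancy in the FLAG strain, 62, 74, 96 and 98% in the untreated HEK293T IP, 36, 74, 90 and 94% in the treated IP, 20, 66, 70 and 84% in treated against untreated enrichment, 58, 84, 92 and 92% in treated against untreated input, 56, 68, 94 and 94% in nc40 at day 0 in mRNA, 62, 68, 94 and 98% in footprints, 48, 62, 86 and 96% in translation efficiency, 56, 84, 100 and 96% in nc40 at day 6 in mRNA, 38, 82, 84 and 94% in footprints, 32, 74, 82 and 84% in translation efficiency, 42, 70, 90 and 94% in the nc40 effect at day 6 against day 0 in mRNA, 34, 66, 76 and 90% in footprints, 60, 78, 94 and 100% in N2 ageing in mRNA, 52, 70, 98 and 96% in footprints, 68, 82, 88 and 98% in YFP-UTR in mRNA, 20, 38, 82 and 94% in footprints and 12, 34, 42 and 52% in translation efficiency. False calls made up 2.33 to 14.5% of edgeR calls, and 0 to 19.6% of DESeq2 calls. camera found each planted list, and lists without change had p of 0.184 to 0.986. Simulated genes varied independently, so these trials could not show how camera treats lists whose members vary together.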

Results

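The samples came from Caenorhabditis elegans and from HEK293T cells, a human embryonic kidney line. GCN1 (GCN-1 in the worm) is a large ribosome-associated protein that binds collided ribosomes and activates the eIF2 kinase GCN2. Ribosome footprints were sequenced from worms carrying 3xFLAG-tagged GCN-1 after a FLAG pull-down (IP) and from the matching input, for footprints of single ribosomes (monosomes) and of paired ribosomes (disomes). An antibody to GCN1 gave IP and input footprints from HEK293T cells, untreated or given 10 nM CC-885 with 20 µg/ml G418 for 4 h. CC-885 is a cereblon modulator that leads to loss of the release factor GSPT1, and G418 is an aminoglycoside that causes stop codon readthrough. Footprints and mRNA were also sequenced from the gcn-1 mutant nc40 and wild type N2 at days 0 and 6 of adulthood (D0 and D6 in the sample titles, with D1 as the first harvest in the protocol) and from strains labelled YFP-UTR and YFP-STOP. Each of these groups had 2 libraries. A 4-thiouridine chase of HEK293T cells labelled WT or GCN1 had 24 samples, 3 at each of 4 chase times per genotype. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries.

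Total counts per library (replicates A and B) were 11430148 and 5604819 in the worm monosome IP and 15430049 and 11690032 in its input. The disome libraries held 51680096 and 43612002 in the IP and 14401801 and 9127164 in the input, and the mRNA libraries of the FLAG strain 9054839 and 10321638. In HEK293T cells the totals were 11221590 and 7995124 in the untreated IP, 8653715 and 6774697 in the untreated input and 4901999 and 4805330 in the treated IP, and 14545409 in replicate B of the treated input. At day 0 they were 15947328 and 14194585 in nc40 mRNA, 16536365 and 16855790 in N2 mRNA, 55511837 and 25017649 in nc40 footprints and 45228497 and 19218091 in N2 footprints. At day 6 they were 37653068 and 42821449 in nc40 mRNA, 43369274 and 44262412 in N2 mRNA, 44091072 and 55046985 in nc40 footprints and 38521183 and 36568381 in N2 footprints. The YFP-STOP and YFP-UTR strains had 23547726 and 21079873 in YFP-STOP mRNA, 20559080 and 20278153 in YFP-UTR mRNA, 1164691 and 653142 in YFP-STOP footprints and 953460 and 804425 in YFP-UTR footprints. These last 4 footprint libraries were the shallowest of the series.

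The monosome IP against its input asked which footprints single ribosomes bound by GCN-1 carry. Footprints of gcn-1 itself (WBGene00021697, chromosome III, 2151945 to 2197908, build WBcel235) rose in the IP by 3.10 (SE 0.0861) on the log2 scale, from 460.2 and 465 counts per 1000000 (CPM) in input to 3703 and 4251 in the IP (n = 2 libraries each). The gene overlaps 4 microRNAs on its strand. Mitochondrially encoded mRNAs and small noncoding RNAs were far above input, as were the cuticle collagen gene col-41 at 4.15 (SE 0.153) and nmgp-1 at 4.39 (SE 0.291), both overlapping another gene. The noncoding genes srpr-2.1 and smy-9 stood at 7.02 (SE 0.557) and 5.05 (SE 0.334). On the low side were the C-type lectin gene clec-10 at -4.91 (SE 0.223), the antimicrobial peptide genes nlp-29 and nlp-28 at -1.64 and -1.58, the RNA-binding protein gene etr-1 at -1.47 and the F-box gene fbxb-90 at -2.66. The rRNA gene rrn-2.1, one of a set of repeated copies, fell by 4.64. Of 12 mitochondrially encoded mRNAs, 12 rose, 0 fell and 0 did not pass, or 12 rose and 0 fell adjusted over the list alone. The median was 4.99, with WBGene00010964 at 5.29 (camera adjusted p = 1.61e-11, and adjusted p = 0.321 with an estimated correlation). Nuclear tRNAs had a median of 3.81, snoRNAs 3.88 and the 2 mitochondrial rRNAs -0.83. rRNA took 4.29% and 2.16% of the IP counts and 11.4% and 9.63% of the input counts.

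Among 83 ribosomal protein genes, 4 rose, 72 fell and 7 did not pass, or 6 rose and 74 fell adjusted over the list alone. The median was -0.49, with rps-22 at -1.01 and rla-2 at -0.87 (camera adjusted p = 1.27e-14, and adjusted p = 0.351 with an estimated correlation). Of 33 proteasome subunit genes, 0 rose, 32 fell and 1 did not pass, or 1 rose and 32 fell adjusted over the list alone. The median was -0.48, with pbs-6 at -0.66 (camera adjusted p = 5.29e-10, and adjusted p = 0.321 with an estimated correlation). Among 51 nuclear genes of the respiratory chain, 1 rose, 43 fell and 7 did not pass, or 1 rose and 43 fell adjusted over the list alone. The median was -0.40, with cox-7C at -0.74 and mev-1 at -0.64 (camera adjusted p = 5.29e-10, and adjusted p = 0.351 with an estimated correlation). Of 29 muscle genes, 0 rose, 23 fell and 6 did not pass, or 1 rose and 23 fell adjusted over the list alone. The median was -0.46, with tnt-2 at -1.06 and mup-2 at -0.82 (camera adjusted p = 1.31e-07, and adjusted p = 0.351 with an estimated correlation). Among 77 sperm genes, 9 rose, 11 fell and 57 did not pass, or 4 rose and 10 fell adjusted over the list alone. The median was -0.31 (turning to 0.07 under library-size scaling), with nspc-10 at -0.95 and nspc-14 at -0.74 (camera adjusted p = 0.0124, and adjusted p = 0.351 with an estimated correlation). nspc genes encode nematode-specific peptides that are in the list by name.

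Of 6 vitellogenin (yolk protein) genes, 4 rose, 0 fell and 2 did not pass, or 4 rose and 0 fell adjusted over the list alone. The median was 0.69, with vit-5 at 1.13 (camera adjusted p = 0.0283, and adjusted p = 0.503 with an estimated correlation). Across 154 members of the chemoreceptor list, 69 rose, 21 fell and 64 did not pass, or 73 rose and 23 fell adjusted over the list alone. The median was 0.92, with srv-28 at 3.53 and srbc-29 at 3.35 (camera adjusted p = 0.00479, and adjusted p = 0.351 with an estimated correlation). That list was built on symbols and also holds srgp-1, a GTPase-activating protein that stood at 0.85 and overlaps other genes. Of 14759 genes tested, 3125 were higher and 2691 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood), and 16 of 25 gene lists passed by camera. DESeq2 called 3819 genes, and edgeR called 3681 without input replicate A and 3641 without input replicate B. Library-size scaling moved the median of all genes, taken from mean log2 CPM, to 0.39.

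The disome IP asked the same of paired ribosomes. gcn-1 stood at -0.07 (SE 0.0802), with 483 and 501 CPM in the IP against 522 and 506 in input, and did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.518). Among the highest of the named genes were uba-2, a subunit of the SUMO-activating enzyme (WBGene00006700, chromosome I, 12741588 to 12749562), at 4.42 (SE 0.114), and eif-2alpha, which encodes the initiation factor subunit that GCN2 phosphorylates (WBGene00021351, chromosome I, 2072680 to 2076925), at 3.79 (SE 0.146). gly-20, taf-7.2 and the germline gene nos-2 stood at 3.96, 3.78 and 3.73, the last with an opposite-strand overlap. Among the lowest were the metallothionein gene mtl-2 at -3.51 (SE 0.144), acbp-3 at -3.42, the galectin gene lec-8 at -3.40, gcsh-1 at -3.23 and the major sperm protein genes msp-55 and msp-51 at -3.41 and -3.27, which belong to a family of near-identical copies. Of 15 basement membrane genes, 12 rose, 0 fell and 3 did not pass, or 13 rose and 0 fell adjusted over the list alone. The median was 1.59, with lam-2 at 2.63 (camera adjusted p = 3.37e-04, and adjusted p = 0.178 with an estimated correlation). Among 275 transporter and channel genes, 122 rose, 18 fell and 135 did not pass, or 117 rose and 18 fell adjusted over the list alone. The median was 0.90, with haf-2 at 2.86 and mrp-1 at 2.66 (camera adjusted p = 2.22e-05, and adjusted p = 0.144 with an estimated correlation). Across 18 genes of the ER unfolded protein response, 15 rose, 1 fell and 2 did not pass, or 15 rose and 1 fell adjusted over the list alone. The median was 0.74, with sel-1 at 1.91 (camera adjusted p = 0.00204, and adjusted p = 0.186 with an estimated correlation). Of 37 genes of mRNA decay and ribosome rescue, 22 rose, 8 fell and 7 did not pass, or 24 rose and 8 fell adjusted over the list alone. The median was 0.60, with smg-1 at 2.49 (camera adjusted p = 0.0188, and adjusted p = 0.178 with an estimated correlation). smg-1 encodes the kinase of nonsense-mediated decay, and gcn-2, the worm kinase that GCN-1 activates, stood at 2.63 with a same-strand overlap.

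Of 83 ribosomal protein genes, 5 rose, 72 fell and 6 did not pass, or 5 rose and 73 fell adjusted over the list alone. The median was -1.10, with rps-28 at -2.72 and rps-24 at -1.90 (camera adjusted p = 2.33e-12, and adjusted p = 0.198 with an estimated correlation). Among 33 proteasome subunit genes, 1 rose, 32 fell and 0 did not pass, or 1 rose and 32 fell adjusted over the list alone. The median was -1.34, with pbs-6 at -2.04 (camera adjusted p = 2.24e-10, and adjusted p = 0.144 with an estimated correlation). For 51 nuclear respiratory chain genes the count was 4 higher, 41 lower and 6 not past, or 4 higher and 42 lower adjusted over the list alone. The median was -0.99, with cox-6A at -2.05 and ucr-11 at -1.69 (camera adjusted p = 2.25e-08, and adjusted p = 0.178 with an estimated correlation). Of 93 sperm genes, 3 rose, 57 fell and 33 did not pass, or 4 rose and 58 fell adjusted over the list alone. The median was -1.58, with msp-81 at -2.82 and msp-76 at -2.32 (camera adjusted p = 2.25e-08, and adjusted p = 0.144 with an estimated correlation). Of 15709 genes tested, 4779 were higher and 4072 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood), and 16 of 25 lists passed. Library-size scaling moved the median of all genes, taken from mean log2 CPM, to 0.47, from 0.11 with TMM.

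Enrichment in both IPs rose with the length of the coding sequence. Across protein-coding genes, which are not independent replicates, Spearman's rho between length and log2 fold change was 0.489 for monosomes (6150 genes) and 0.555 for disomes (6435 genes). In the fifth with the shortest sequences the median was -0.37 for monosomes and -1.06 for disomes, and in the fifth with the longest 0.20 and 1.24. With the trend on length removed, list medians were 0.22 for vitellogenin genes in monosomes and, in disomes, 0.29 for transporter and channel genes, 0.42 for the ER response, -0.61 for ribosomal protein genes, -0.01 for basement membrane genes and, with the direction turned, -0.23 for mRNA decay and rescue genes (cameraPR adjusted p = 0.637). Of 4060 genes past the threshold in both IPs, 3765 had the same direction and 295 the opposite one. Unrelated calls would give about 833 genes higher in both and 749 lower in both, against 1797 and 1968 seen (Pearson's r across 13852 genes 0.391).

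**Figure D1:**
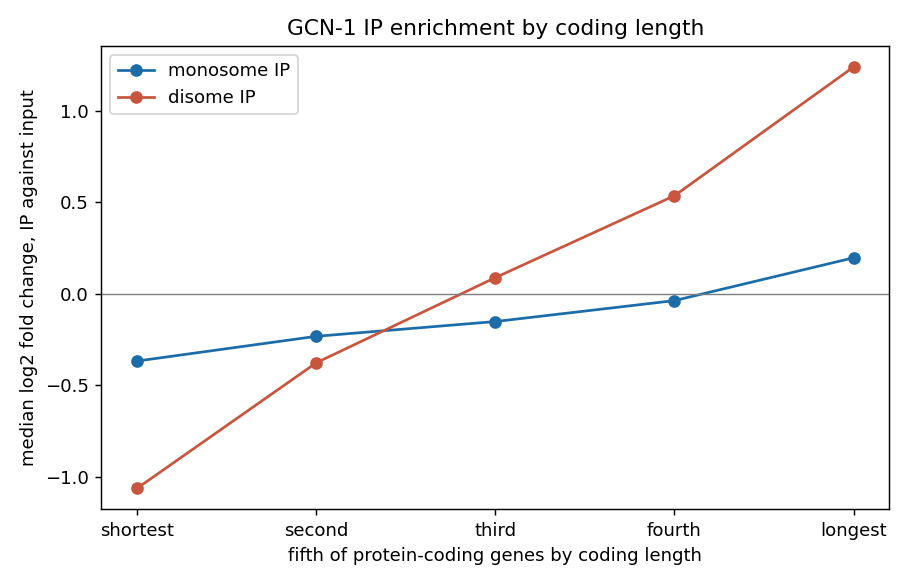
Median log2 fold change of IP over input (vertical axis) in 5 equal groups of protein-coding genes in order of coding length (horizontal axis), for the monosome IP (blue) and the disome IP (red). The medians go from -0.37 to 0.20 in monosomes and from -1.06 to 1.24 in disomes.

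**Figure D2:**
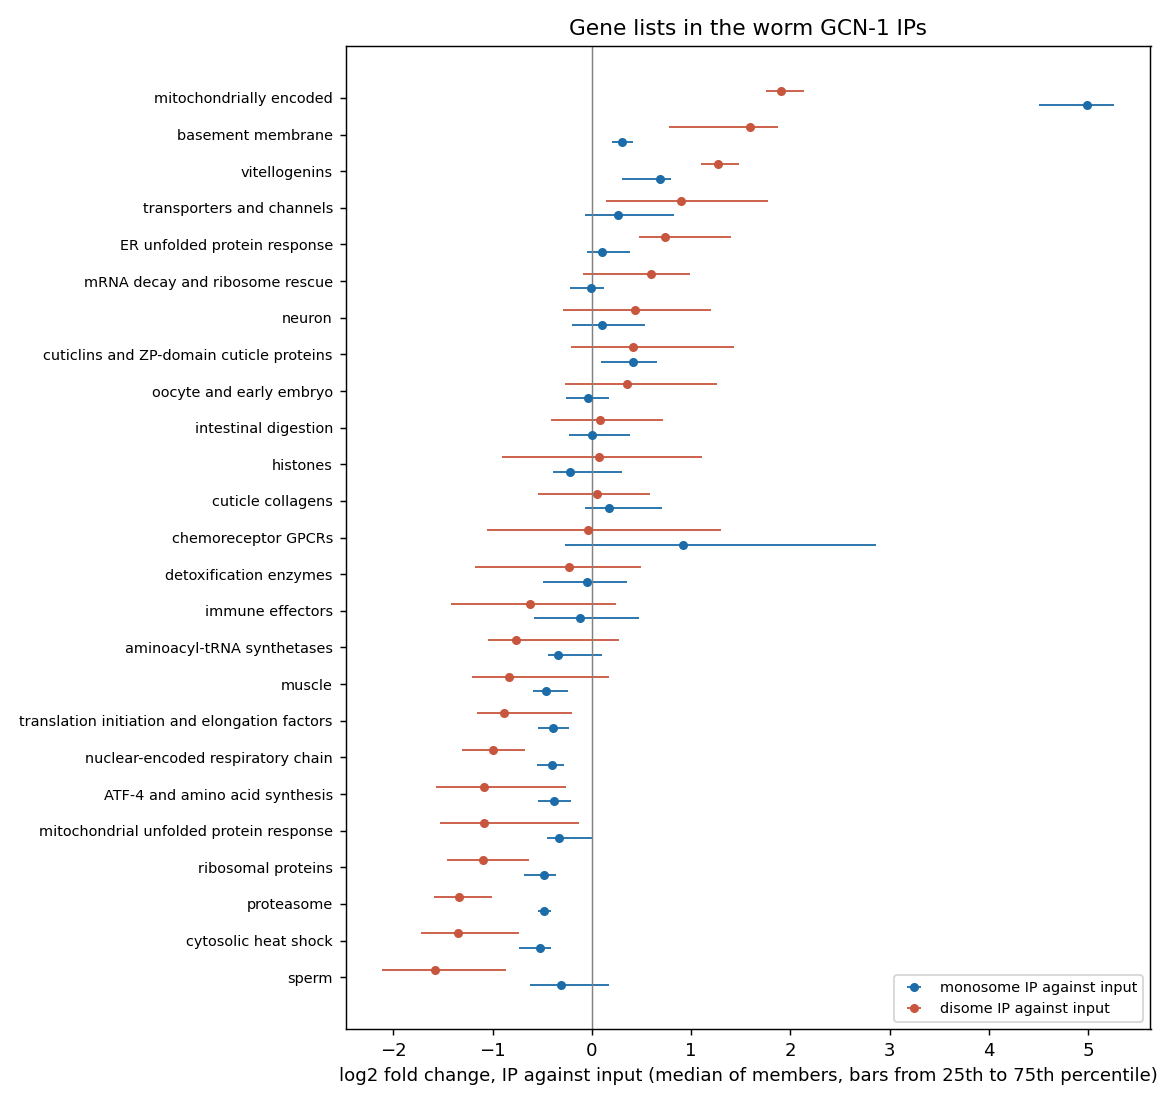
Log2 fold change of IP over input (horizontal axis) for the fixed gene lists (vertical axis) in the worm monosome IP (blue) and disome IP (red), with points at the median of the members and bars from the 25th to the 75th percentile. Mitochondrially encoded mRNAs lie at 4.99 and 1.91, and proteasome genes at -0.48 and -1.34.

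Whether enrichment differed between disomes and monosomes was tested as an interaction over the 8 libraries. gcn-1 was lower in the disome enrichment by -3.21 (SE 0.111), and uba-2, taf-7.2 and eif-2alpha were higher by 4.33 (SE 0.132), 4.11 and 3.95 (SE 0.169). The noncoding RNA gene mrpr-1 stood at -5.74, the lectin gene clec-10 at 4.94, and the yolk receptor gene rme-2 at 2.22. Of 12 mitochondrial mRNAs, 0 rose, 12 fell and 0 did not pass, or 0 rose and 12 fell adjusted over the list alone. The median was -3.09, with COX3 at -3.77 (camera adjusted p = 4.07e-09, and adjusted p = 0.0595 with an estimated correlation). Among 33 proteasome genes, 0 rose, 32 fell and 1 did not pass, or 0 rose and 32 fell adjusted over the list alone. The median was -0.87, with pbs-6 at -1.43 (camera adjusted p = 2.06e-09, and adjusted p = 0.0772 with an estimated correlation). Of 41 oocyte and early embryo genes, 20 rose, 6 fell and 15 did not pass, or 20 rose and 7 fell adjusted over the list alone. The median was 0.31, with rme-2 at 2.22 (camera adjusted p = 0.00233, and adjusted p = 0.269 with an estimated correlation). Of 16025 genes tested, 3333 were higher and 3337 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood), with 16 of 25 lists past it.

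Ribosome occupancy in the FLAG strain, the monosome input against mRNA, was 2.00 (SE 0.0666) for gcn-1, with 513 and 515 CPM of footprints and 139 and 118.7 CPM of mRNA. Most histone and respiratory chain genes had more footprints than mRNA, and yolk protein genes had fewer. The sex determination gene fem-3 and the long noncoding RNA gene tts-1 were among the lowest at -8.33 and -10.45. The histone gene his-16 was at least 9.15 higher, since it had no mRNA counts. Of 32 histone genes (most in multi-copy families), 31 rose, 1 fell and 0 did not pass, or 31 rose and 1 fell adjusted over the list alone. The median was 6.08, with his-64 at 8.25 and his-62 at 7.91 (camera adjusted p = 3.15e-11, and adjusted p = 0.226 with an estimated correlation). Replication-dependent histone mRNAs end in a stem-loop and not in a poly(A) tail. Among 6 vitellogenin genes, 0 rose, 6 fell and 0 did not pass, or 0 rose and 6 fell adjusted over the list alone. The median was -3.13, with vit-5 at -3.94 (camera adjusted p = 0.00288, and adjusted p = 0.410 with an estimated correlation). Among 51 respiratory chain genes, 50 rose, 1 fell and 0 did not pass, or 50 rose and 1 fell adjusted over the list alone. The median was 1.43, with ucr-11 at 3.17 and cox-6A at 2.65 (camera adjusted p = 3.15e-11, and adjusted p = 0.286 with an estimated correlation). Of 13697 genes tested, 5462 were higher and 5249 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood), and library-size scaling moved the all-gene median to -0.63. Spearman's rho with coding length was -0.373 (6792 genes), with medians of 0.88 in the fifth with the shortest and -0.60 in that with the longest. The comparison shares its input libraries with the monosome IP comparison.

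In HEK293T cells the GCN1 IP was set against input footprints without and with CC-885 and G418. No human gene names were at hand, so the targeted genes GCN1, GSPT1, GSPT2 and ETF1 could not be located. Among the genes named, untreated cells had ENSG00000209702 and ENSG00000200496 highest in the IP, at 8.69 (6.84 to 11.74) as the log2 ratio of summed counts with its 95% counting interval, from 2 counts in input, and at 8.18 (SE 0.361), and ENSG00000202347 and ENSG00000203413 lowest at -6.53 (SE 0.249) and -6.27 (SE 0.199). Of 14878 genes tested, 3609 were higher and 3012 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood, n = 2 libraries per group). Treated cells had ENSG00000239580 and ENSG00000099834 highest at 9.78 (7.29 to 15.08), from 1 count in input, and 8.60 (SE 0.342), and ENSG00000200615 and ENSG00000202347 lowest at -7.34 (-10.38 to -5.47), from 2 counts in the IP, and -6.23 (SE 0.207). There 4762 of 15482 genes were higher and 4193 lower. Of 5257 genes past the threshold in both conditions, 5170 had the same direction and 87 the opposite, against 1028 and 833 from unrelated calls in the higher and lower sets of 2864 and 2306 (r across genes 0.863). DESeq2 called 4324 genes untreated and 4850 treated. With no filter beyond 1 count edgeR called 0 treated (10029 at an unadjusted p under 0.05), and the untreated count was 4296 without input replicate A and 4199 without input replicate B. The treated fits rested on 1 input library and 1 residual degree of freedom, and took their spread from the 2 IP libraries.

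The difference between treated and untreated IP enrichment was tested as an interaction. ENSG00000260239 and ENSG00000100697 were among the largest gains at 4.62 (SE 0.389) and 4.39 (SE 0.501), and ENSG00000273542 and ENSG00000117984 among the largest losses at -2.80 (SE 0.508) and -1.81 (SE 0.292). Of 17354 genes tested, 1458 were higher and 1903 lower at the Benjamini-Hochberg threshold, and with RLE factors 1737 were higher and 1272 lower, which turned the balance. DESeq2 called 1719 genes, and edgeR 1908 without untreated IP replicate A, 1994 without untreated input replicate A, 1824 without its replicate B and 0 with treated input replicate A as deposited (2964 at an unadjusted p under 0.05). In input footprints, treatment went with ENSG00000273542 and ENSG00000120738 higher by 8.48 and 8.33, and ENSG00000100697 and ENSG00000235034 lower, at -6.41 and -2.20. With 1 treated library the spread came from the 2 untreated ones, which were apart for ENSG00000273542 (0.586 and 0.148 CPM against 145 treated) and ENSG00000100697 (17707 and 6477 against 142). There 3612 of 15777 genes were higher and 3798 lower (edgeR quasi-likelihood), and DESeq2 called 2469 genes. The enrichment is taken over these input libraries.

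mRNA half-lives in HEK293T cells labelled WT or GCN1 came from 1 deposited table each, which pooled the chase, without replicate error. The labels do not define the GCN1 genotype. R squared was over 0.7 for 7478 genes in WT and 4483 in GCN1. Half-lives positive in both (12302 genes) had a median of 5.79 in WT and 8.68 in GCN1 and a median log2 ratio of 0.63. In GCN1 84.3% were longer (95% exact binomial interval 83.7 to 85.0%, as if genes were independent). Genes enriched in the untreated IP had a median ratio of 0.690, percentile 96.9 of random lists matched for half-life (central 95% 0.636 to 0.691). Depleted genes had 0.621, below all theirs (0.661 to 0.716). Both lists use other libraries of this series. Matching was on half-life and not abundance, so the percentiles cannot be credited to the IP. Among half-lives within 0.5 to 24 in both genotypes the largest ratios were ENSG00000010379 at 4.46 and ENSG00000262304 at 4.40, and the smallest ENSG00000197653 at -4.71 and ENSG00000148488 at -4.29, all from fits with R squared of 0.0176 or less in the poorer genotype. Centring leaves 50% longer by construction.

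**Figure D3:**
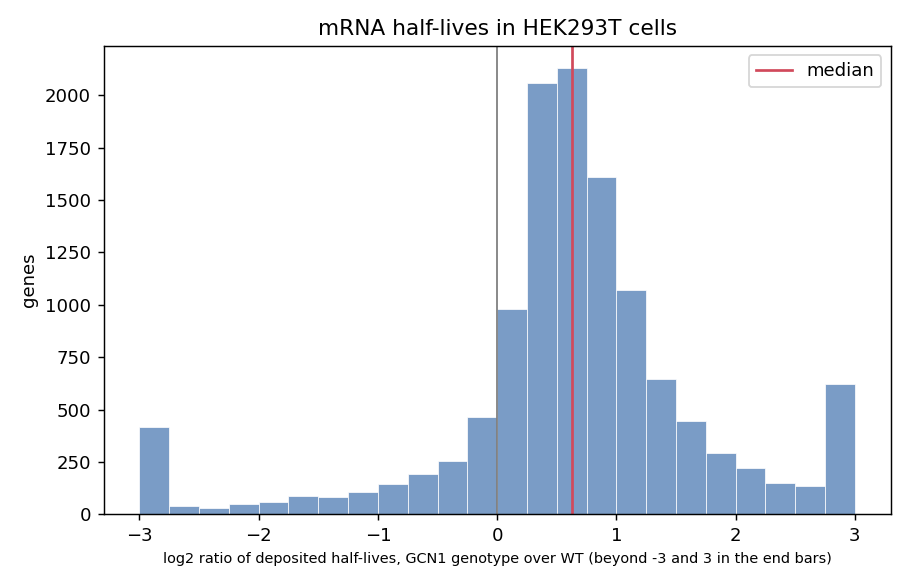
Number of genes (vertical axis) by log2 ratio of the deposited half-life in GCN1 over WT HEK293T cells (horizontal axis, end bars hold values beyond -3 and 3), with a grey line at 0 and a red line at the median. The median of the 12302 genes is 0.63.

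Day 0 nc40 worms were compared with N2 in mRNA and in footprints. gcn-1 mRNA was -0.24 (SE 0.0431), at 147 and 163 CPM in nc40 and 186 and 179 in N2, and its footprints -0.35 (SE 0.0415), at 641 and 649 and 827 and 819.9 CPM. The labels do not say what the allele changes. In mRNA, most cuticle collagen and digestive genes were higher and most oocyte genes slightly lower. The collagen genes col-81 and col-139 stood at 1.75 (SE 0.0606) and 1.44, the esterase gene cest-1.1 at 1.62, and the daf-2-regulated genes pud-3 and pud-4 at -2.40 (SE 0.0516) and -2.20. Of 129 cuticle collagen genes, 99 rose, 6 fell and 24 did not pass, or 105 rose and 6 fell adjusted over the list alone. The median was 1.08, with col-129 at 1.48 (camera adjusted p = 2.76e-24, and adjusted p = 0.183 with an estimated correlation). Among 78 sperm genes, 32 rose, 2 fell and 44 did not pass, or 35 rose and 2 fell adjusted over the list alone. The median was 0.69, with gsp-3 at 1.57 and msp-36 at 1.02 (camera adjusted p = 3.64e-10, and adjusted p = 0.183 with an estimated correlation). Across 41 oocyte and early embryo genes, 0 rose, 37 fell and 4 did not pass, or 0 rose and 38 fell adjusted over the list alone. The median was -0.17, with rme-2 at -0.32 and cey-2 at -0.22 (camera adjusted p = 2.12e-11, and adjusted p = 0.186 with an estimated correlation). Of 28 intestinal digestion genes, 17 rose, 5 fell and 6 did not pass, or 17 rose and 5 fell adjusted over the list alone. The median was 0.29, with cpr-4 at 1.23 and asp-6 at 0.55 (camera adjusted p = 0.00131, and adjusted p = 0.183 with an estimated correlation). Of 13921 genes tested, 1696 were higher and 1765 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood), with 14 of 27 lists past it. DESeq2 called 1744 genes.

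Footprints at day 0 in nc40 were higher for most sperm genes. msp-10 stood at 1.94 (SE 0.0940), spch-1 at 1.85 and ssq-3 at 1.68, and the esterase gene cest-31 was among the lowest at -1.61 (SE 0.0773). Of 89 sperm genes (many in near-identical copies), 64 rose, 2 fell and 23 did not pass, or 68 rose and 2 fell adjusted over the list alone. The median was 1.40, with msp-40 at 1.52 and nspd-2 at 1.56 (camera adjusted p = 5.94e-16, and adjusted p = 0.197 with an estimated correlation). Among 113 cuticle collagen genes, 72 rose, 9 fell and 32 did not pass, or 75 rose and 12 fell adjusted over the list alone. The median was 1.06, with col-133 at 2.84 and col-129 at 1.51 (camera adjusted p = 1.37e-07, and adjusted p = 0.276 with an estimated correlation). Across 41 oocyte genes, 1 rose, 32 fell and 8 did not pass, or 2 rose and 34 fell adjusted over the list alone. The median was -0.24, with glh-4 at -0.50 and cey-2 at -0.45 (camera adjusted p = 1.25e-08, and adjusted p = 0.370 with an estimated correlation). Of 31 aminoacyl-tRNA synthetase genes, 0 rose, 21 fell and 10 did not pass, or 0 rose and 22 fell adjusted over the list alone. The median was -0.26, with aars-2 at -0.42 (camera adjusted p = 7.99e-08, and adjusted p = 0.276 with an estimated correlation). Among 12 mitochondrial mRNAs, 9 rose, 0 fell and 3 did not pass, or 10 rose and 0 fell adjusted over the list alone. The median was 0.76, with COX3 at 0.99 (camera adjusted p = 0.00816, and adjusted p = 0.615 with an estimated correlation). Of 2623 genes depleted in the monosome GCN-1 IP, 558 rose, 931 fell and 1134 did not pass, or 583 rose and 1000 fell adjusted over the list alone. The median was -0.08 (turning to 0.06 under library-size scaling), the mean 0.04 and the direction of the test down (camera adjusted p = 0.00226, and adjusted p = 0.488 with an estimated correlation). That last list was chosen on other libraries of this series. Of 14259 genes tested, 2841 were higher and 2279 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood), and DESeq2 called 3390. Library-size scaling moved the all-gene median to 0.15.

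Translation efficiency, footprints over mRNA, was -0.06 (SE 0.0635) for gcn-1 in nc40 over N2 at day 0 and did not pass the test. pud-3, whose mRNA was lower, stood at 3.65 (SE 0.0883), with the lysozyme gene ilys-5 at 2.05 and the carbonic anhydrase gene cah-4 at 1.93. Of 133 cuticle collagen genes, 14 rose, 22 fell and 97 did not pass, or 18 rose and 26 fell adjusted over the list alone. The median was -0.24, with dpy-17 at -0.95 and dpy-14 at -0.97 (camera adjusted p = 4.67e-04, and adjusted p = 0.188 with an estimated correlation). Among 87 sperm genes, 12 rose, 1 fell and 74 did not pass, or 20 rose and 1 fell adjusted over the list alone. The median was 0.49, with spe-6 at 1.26 (camera adjusted p = 9.12e-04, and adjusted p = 0.188 with an estimated correlation). Across 12 mitochondrial mRNAs, 11 rose, 0 fell and 1 did not pass, or 11 rose and 0 fell adjusted over the list alone. The median was 0.73, with WBGene00010963 at 0.95 (camera adjusted p = 4.48e-04, and adjusted p = 0.394 with an estimated correlation). Of 15090 genes tested, 1048 were higher and 565 lower at the Benjamini-Hochberg threshold, and with RLE factors 735 and 853. DESeq2 called 1020 genes, and edgeR 990 without N2 footprint replicate A, 1019 without N2 mRNA replicate A and 1065 without its replicate B. Of 1873 genes past the threshold in both mRNA and footprints, 1656 had the same direction (r across genes 0.497).

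At day 6 gcn-1 mRNA in nc40 was -0.13 (SE 0.0912) and did not pass the test, at 110.3 and 105 CPM against 107 and 128 in N2, and its footprints were -0.32 (SE 0.0297), at 336 and 334 and 416 and 419 CPM. Most yolk protein, digestive and muscle genes were higher in nc40 mRNA. In mRNA col-165 (WBGene00000738, chromosome X, 4353618 to 4354852) stood at 5.36, with 0.549 and 1.05 CPM in N2, col-93 at 4.84 (SE 0.122) with an opposite-strand overlap, and the glucuronosyltransferase gene ugt-63 at 4.07 (SE 0.111). The apoptosis activator gene egl-1 stood at -2.26 (SE 0.0924) and the C-type lectin gene clec-196 at -2.47. Of 29 intestinal digestion genes, 28 rose, 0 fell and 1 did not pass, or 28 rose and 0 fell adjusted over the list alone. The median was 1.53, with cpr-1 at 2.37 and lipl-5 at 2.33 (camera adjusted p = 6.61e-12, and adjusted p = 0.381 with an estimated correlation). Among 6 vitellogenin genes, 6 rose, 0 fell and 0 did not pass, or 6 rose and 0 fell adjusted over the list alone. The median was 2.35, with vit-1 at 3.07 (camera adjusted p = 3.63e-04, and adjusted p = 0.405 with an estimated correlation). Across 29 muscle genes, 23 rose, 1 fell and 5 did not pass, or 25 rose and 1 fell adjusted over the list alone. The median was 0.82, with tnt-4 at 2.21 and myo-2 at 2.00 (camera adjusted p = 6.94e-07, and adjusted p = 0.381 with an estimated correlation). Among 12 mitochondrial mRNAs, 12 rose, 0 fell and 0 did not pass, or 12 rose and 0 fell adjusted over the list alone. The median was 1.00, with WBGene00010963 at 1.21 (camera adjusted p = 5.47e-05, and adjusted p = 0.381 with an estimated correlation). Of 405 members of the chemoreceptor list, 34 rose, 173 fell and 198 did not pass, or 34 rose and 170 fell adjusted over the list alone. The median was -0.66, with sri-43 at -2.75 (camera adjusted p = 2.65e-06, and adjusted p = 0.381 with an estimated correlation).

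Of 178 detoxification enzyme genes, 97 rose, 29 fell and 52 did not pass, or 97 rose and 29 fell adjusted over the list alone. The median was 0.44, with ugt-41 at 2.47 and cyp-29A4 at 2.65 (camera adjusted p = 5.17e-06, and adjusted p = 0.381 with an estimated correlation). Among 19 heat shock genes, 15 rose, 0 fell and 4 did not pass, or 16 rose and 0 fell adjusted over the list alone. The median was 0.64 (camera adjusted p = 1.08e-04, and adjusted p = 0.405 with an estimated correlation). Among 290 immune effector genes, 131 rose, 87 fell and 72 did not pass, or 133 rose and 94 fell adjusted over the list alone. The median was 0.19 (turning to -0.07 under library-size scaling), with dod-24 at 2.93 and clec-66 at 3.64 (camera adjusted p = 0.0497, and adjusted p = 0.427 with an estimated correlation, and adjusted p = 0.0600 with the replicate block). Of 18687 genes tested, 5522 were higher and 5581 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood), and 21 of 27 lists passed. Library-size scaling moved the all-gene median to -0.29.

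Footprints at day 6 were higher in nc40 for most muscle, collagen and respiratory chain genes and lower for most histone genes. They had cdr-3, gskl-2 and oac-32 among the highest, at 8.97, 7.39 (SE 0.106) and 7.20 (SE 0.0820). Mean mRNA of cdr-3 was 0.183 CPM in nc40 and 0.252 in N2. The sodium-calcium exchanger gene ncx-5 and the guanylyl cyclase gene gcy-3 stood at -3.70 (SE 0.0881) and -3.11. Of 29 muscle genes, 29 rose, 0 fell and 0 did not pass, or 29 rose and 0 fell adjusted over the list alone. The median was 1.09, with myo-2 at 3.37 (camera adjusted p = 5.04e-11, and adjusted p = 0.330 with an estimated correlation). Among 147 cuticle collagen genes, 121 rose, 5 fell and 21 did not pass, or 127 rose and 5 fell adjusted over the list alone. The median was 2.58, with col-165 at 7.44 and col-10 at 5.45 (camera adjusted p = 2.23e-21, and adjusted p = 0.113 with an estimated correlation). Across 51 nuclear respiratory chain genes, 46 rose, 0 fell and 5 did not pass, or 46 rose and 0 fell adjusted over the list alone. The median was 0.42, with sdha-1 at 1.00 (camera adjusted p = 2.61e-09, and adjusted p = 0.330 with an estimated correlation). Among 34 histone genes, 2 rose, 26 fell and 6 did not pass, or 2 rose and 27 fell adjusted over the list alone. The median was -0.95, with his-2 at -1.53 and his-62 at -1.52 (camera adjusted p = 3.25e-07, and adjusted p = 0.330 with an estimated correlation). Of 16450 genes tested, 5164 were higher and 5132 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood).

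In translation efficiency at day 6, most yolk protein and heat shock genes were lower in nc40. gcn-1 was -0.21 (SE 0.109) and did not pass the test. The ground-like gene grl-7 was lower at -4.73 (SE 0.230). Of 6 vitellogenin genes, 0 rose, 6 fell and 0 did not pass, or 0 rose and 6 fell adjusted over the list alone. The median was -1.09, with vit-5 at -1.53 and vit-1 at -1.02 (camera adjusted p = 0.00843, and adjusted p = 0.500 with an estimated correlation). Among 167 cuticle collagen genes, 85 rose, 7 fell and 75 did not pass, or 91 rose and 8 fell adjusted over the list alone. The median was 1.06 (camera adjusted p = 8.15e-14, and adjusted p = 0.262 with an estimated correlation). Across 19 heat shock genes, 3 rose, 12 fell and 4 did not pass, or 3 rose and 13 fell adjusted over the list alone. The median was -0.70, with hsp-16.2 at -1.36 and hsf-1 at -0.67 (camera adjusted p = 0.00306, and adjusted p = 0.500 with an estimated correlation). Of 19395 genes tested, 2341 were higher and 3983 lower at the Benjamini-Hochberg threshold, and library-size scaling moved the all-gene median to 0.24. Of 6745 genes past the threshold in both assays, 5724 had the same direction.

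Whether the nc40 difference itself changed from day 0 to day 6 was tested as an interaction. gcn-1 was 0.04 (SE 0.110) in mRNA and 0.03 (SE 0.0506) in footprints and passed neither test. col-165 had a larger difference at day 6 by 5.33 in mRNA, and the acyl-CoA synthetase gene acs-2 and the flavin monooxygenase gene fmo-2 a lower one at -3.15 (SE 0.128) and -2.86. Of 29 intestinal digestion genes in mRNA, 23 rose, 1 fell and 5 did not pass, or 24 rose and 1 fell adjusted over the list alone. The median was 1.24, with asp-14 at 3.25 and asp-3 at 2.49 (camera adjusted p = 5.57e-11, and adjusted p = 0.167 with an estimated correlation). Among 6 vitellogenin genes in mRNA, 6 rose, 0 fell and 0 did not pass, or 6 rose and 0 fell adjusted over the list alone. The median was 2.38, with vit-1 at 3.22 (camera adjusted p = 8.86e-06, and adjusted p = 0.219 with an estimated correlation). Across 93 sperm genes in mRNA, 6 rose, 47 fell and 40 did not pass, or 6 rose and 53 fell adjusted over the list alone. The median was -1.22, with nspd-2 at -2.02 (camera adjusted p = 3.27e-07, and adjusted p = 0.0953 with an estimated correlation). Of 151 cuticle collagen genes in footprints, 96 rose, 3 fell and 52 did not pass, or 100 rose and 4 fell adjusted over the list alone. The median was 1.96, with col-20 at 3.57 (camera adjusted p = 4.20e-20, and adjusted p = 0.00361 with an estimated correlation). Among 31 aminoacyl-tRNA synthetase genes in footprints, 25 rose, 0 fell and 6 did not pass, or 26 rose and 0 fell adjusted over the list alone. The median was 0.37 (camera adjusted p = 5.14e-08, and adjusted p = 0.0404 with an estimated correlation). Across 162 detoxification enzyme genes in footprints, 51 rose, 16 fell and 95 did not pass, or 51 rose and 16 fell adjusted over the list alone. The median was 0.35, with gst-26 at 1.60 and gst-24 at -3.69 (camera adjusted p = 3.48e-04, and adjusted p = 0.0404 with an estimated correlation). Of 17902 genes tested, 2922 were higher and 3026 lower at the Benjamini-Hochberg threshold in mRNA, and with RLE factors 3659 and 2444. In footprints 3579 of 17176 were higher and 3816 lower. Library-size scaling moved the all-gene medians to -0.32 and -0.19.

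N2 at day 6 against day 0 may mix age with batch, as count tables were separate. gcn-1 mRNA stood at -0.86 (SE 0.0789), from 209.5 and 202 to 103 and 123.3 CPM. Its footprints were -1.59 (SE 0.0516), from 1020.4 and 969.8 to 329.7 and 332. Most immune and neuronal genes were higher, and most yolk protein, oocyte, muscle and mitochondrial genes lower. The lysozyme gene ilys-3 had no counts at day 0 and was at least 9.66 higher in mRNA, and eol-1 stood at 8.97, from 0.138 and 0.473 CPM. Lower were col-93 at -7.15 (SE 0.104), pud-3 at -6.01 and vit-1 at -5.72. Of 41 oocyte and early embryo genes, 2 rose, 39 fell and 0 did not pass, or 2 rose and 39 fell adjusted over the list alone. The median was -2.37, with puf-5 at -2.73 and rme-2 at -2.99 (camera adjusted p = 3.30e-12, and adjusted p = 0.421 with an estimated correlation). Among 6 vitellogenin genes, 0 rose, 6 fell and 0 did not pass, or 0 rose and 6 fell adjusted over the list alone. The median was -3.66 (camera adjusted p = 0.00166, and adjusted p = 0.453 with an estimated correlation). Across 29 muscle genes, 2 rose, 26 fell and 1 did not pass, or 2 rose and 26 fell adjusted over the list alone. The median was -1.30, with tnt-2 at -3.46 (camera adjusted p = 6.71e-07, and adjusted p = 0.413 with an estimated correlation). Of 12 mitochondrial mRNAs, 0 rose, 12 fell and 0 did not pass, or 0 rose and 12 fell adjusted over the list alone. The median was -2.93 (camera adjusted p = 5.40e-06, and adjusted p = 0.257 with an estimated correlation). Of 271 immune effector genes, 190 rose, 35 fell and 46 did not pass, or 190 rose and 35 fell adjusted over the list alone. The median was 1.71, or 1.69 with the 26 members that had a group at 0 set to their bound, with lys-7 at 4.48 and irg-4 at 4.67 (camera adjusted p = 2.80e-05, and adjusted p = 0.273 with an estimated correlation). Across 54 neuronal genes, 41 rose, 6 fell and 7 did not pass, or 41 rose and 6 fell adjusted over the list alone. The median was 1.36, with flp-5 at 3.65 and flp-15 at 3.77 (camera adjusted p = 7.54e-04, and adjusted p = 0.257 with an estimated correlation). Of 17806 genes tested, 8360 were higher and 6237 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood). Library-size scaling moved the all-gene median to 0.71 and RLE to 0.25, from 0.34 with TMM.

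Footprints with age had srh-252 and ilys-3 among the highest, each from 2 counts at day 0, with log2 ratios of summed counts and 95% counting intervals of 13.70 (11.84 to 16.74) and 11.10 (9.25 to 14.14), and cdr-3, gskl-2 and oac-32 among the lowest at -11.24 (SE 0.134), -11.01 and -9.89. Of 82 ribosomal protein genes, 2 rose, 80 fell and 0 did not pass, or 2 rose and 80 fell adjusted over the list alone. The median was -1.53, with rla-0 at -1.99 and rpl-25.1 at 2.54 (camera adjusted p = 4.31e-17, and adjusted p = 0.466 with an estimated correlation). Among 31 aminoacyl-tRNA synthetase genes, 0 rose, 31 fell and 0 did not pass, or 0 rose and 31 fell adjusted over the list alone. The median was -1.19, with lars-1 at -1.56 (camera adjusted p = 5.41e-09, and adjusted p = 0.468 with an estimated correlation). Of 82 sperm genes, 15 rose, 61 fell and 6 did not pass, or 15 rose and 61 fell adjusted over the list alone. The median was -2.82, with nspc-10 at 3.62 (camera adjusted p = 1.22e-06, and adjusted p = 0.316 with an estimated correlation). Of 16010 genes, 7046 were higher and 6003 lower (edgeR quasi-likelihood). Library-size scaling moved the all-gene median to 0.85, from 0.19 with TMM.

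The nc40 difference at day 6 ran against the change with age. In mRNA, 5742 of 8947 genes past the threshold in both comparisons had opposite directions. Genes higher with age and lower in nc40 numbered 3383 and the reverse 2359, where unrelated calls would give 2521 and 1888. In footprints 5809 of 8415 had opposite directions, 3348 and 2461 against 2285 and 1769. Both comparisons use the N2 day 6 libraries, so part of the excess may come from those shared controls. The covariance across genes, which are not independent replicates, was -0.80 in mRNA and -1.02 in footprints (r -0.406 and -0.490), beside -0.0124 and -0.0260 (r -0.383 and -0.481) in simulations with no change but the shared libraries. With a different N2 day 6 replicate in each comparison the covariances were -0.517 and -0.582 in mRNA and -0.819 and -0.821 in footprints.

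**Figure D4:**
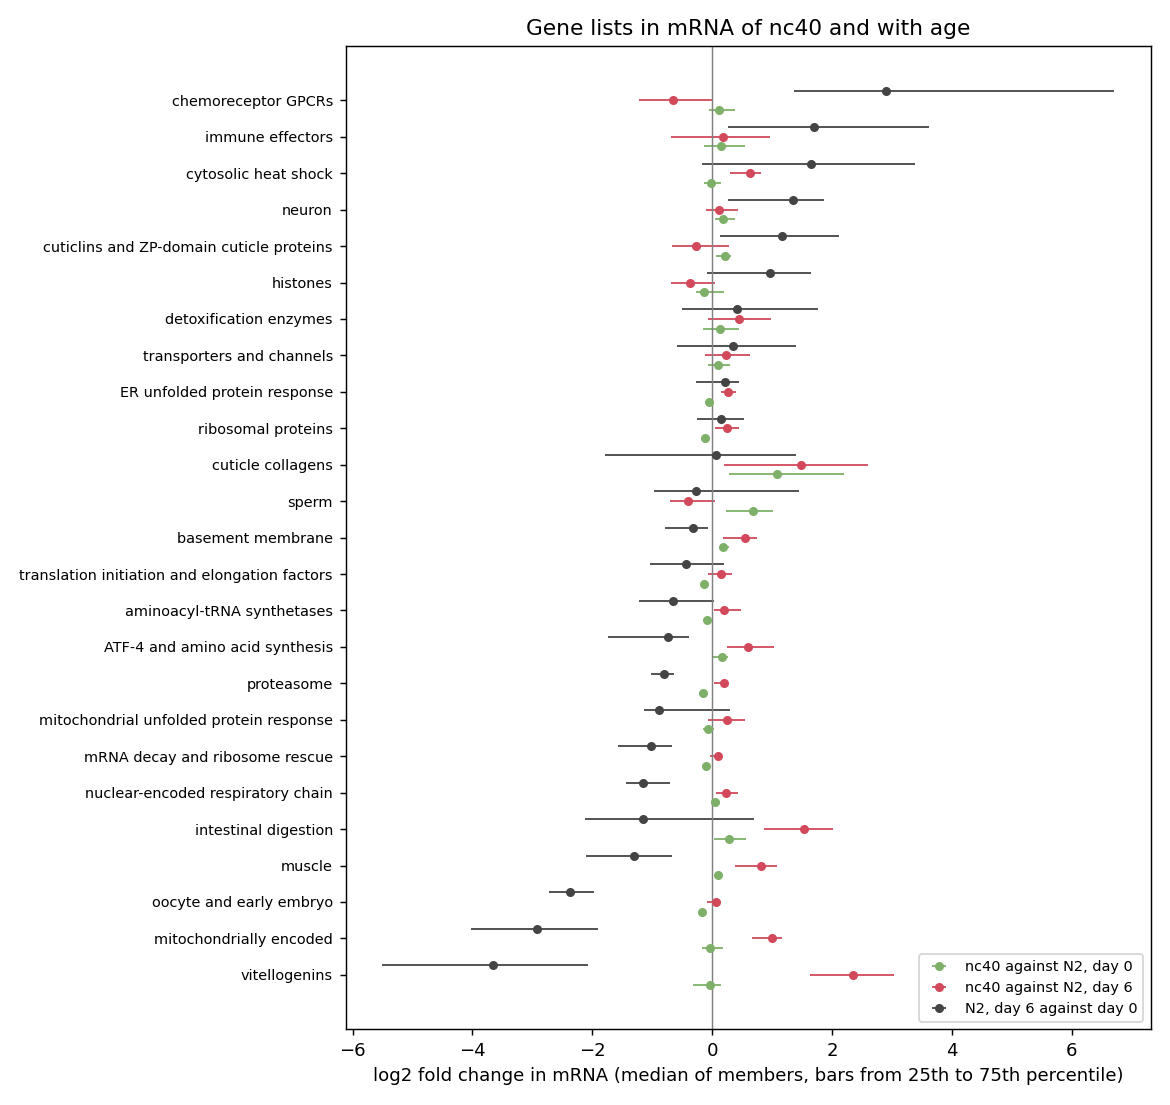
Log2 fold change in mRNA (horizontal axis) of the fixed gene lists (vertical axis) for nc40 against N2 at day 0 (green) and day 6 (red) and for N2 at day 6 against day 0 (dark grey), with points at the median of the members and bars from the 25th to the 75th percentile. Vitellogenin genes lie at -0.03, 2.35 and -3.66, and muscle genes at 0.10, 0.82 and -1.30.

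The YFP-UTR strain was compared with YFP-STOP. The series title concerns readthrough of stop codons. gcn-1 stood at 0.07 (SE 0.0397) in mRNA, with 161 and 160.3 CPM against 148 and 157, and at -0.02 (SE 0.106) in footprints, with 496 and 511 against 476 and 549, and passed neither test. The YFP reporter was lower in YFP-UTR by -1.45 (SE 0.0187) in mRNA, at 10276 and 10352 CPM against 28417 and 27847, and by -2.23 (SE 0.130) in footprints, at 5669 and 4777 CPM against 22405 and 26545. The small heat shock genes hsp-16.41 (WBGene00002018, chromosome V, 1805178 to 1805875) and hsp-16.2 (WBGene00002016, chromosome V, 1804334 to 1804957), members of a family of similar copies, rose by 6.15 (SE 0.156) and 5.39 (SE 0.156) in mRNA. In footprints they had 2 counts each over both YFP-STOP libraries, and the log2 ratios of summed counts, with 95% counting intervals, were 6.59 (4.71 to 9.64) and 6.76 (4.89 to 9.81). The HSP70 gene hsp-70 (WBGene00002026, chromosome I, 9320325 to 9322519), with an opposite-strand overlap, rose by 4.03 (SE 0.0998) and 4.32 (SE 0.255), and the myosin chaperone gene unc-45, which overlaps other genes, by 0.68 (SE 0.0447) and 0.78 (SE 0.145). Lower in mRNA were the arginine kinase gene argk-1 at -2.88, the cytochrome P450 gene cyp-35C1 at -2.70, the protease gene asp-14 at -2.07 and the cathepsin B-like gene cpr-3 at -1.66.

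Of 15 heat shock genes in mRNA, 7 rose, 1 fell and 7 did not pass, or 8 rose and 1 fell adjusted over the list alone. The median was 0.16 (camera adjusted p = 6.16e-04, and adjusted p = 0.308 with an estimated correlation). Among 144 detoxification enzyme genes, 4 rose, 46 fell and 94 did not pass, or 6 rose and 53 fell adjusted over the list alone. The median was -0.24, with cyp-35A2 at -1.79 (camera adjusted p = 1.89e-07, and adjusted p = 0.234 with an estimated correlation). Across 84 sperm genes, 40 rose, 1 fell and 43 did not pass, or 43 rose and 1 fell adjusted over the list alone. The median was 0.61, with msp-36 at 0.79 and msp-76 at 0.84 (camera adjusted p = 1.03e-11, and adjusted p = 0.138 with an estimated correlation). Of 14321 genes tested, 1414 were higher and 1232 lower at the Benjamini-Hochberg threshold (edgeR quasi-likelihood). DESeq2 called 1360 genes, and edgeR 1734 without YFP-UTR replicate B and 1759 without YFP-STOP replicate A. Spearman's rho with coding length was 0.442 (6654 genes), with medians of -0.08 in the fifth with the shortest and 0.09 in that with the longest.

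Of 12 heat shock genes in footprints, 3 rose, 0 fell and 9 did not pass, or 3 rose and 0 fell adjusted over the list alone. The median was 0.17 (camera adjusted p = 8.83e-05, and adjusted p = 0.605 with an estimated correlation). Among 82 ribosomal protein genes in footprints, 2 rose, 0 fell and 80 did not pass, or 6 rose and 0 fell adjusted over the list alone. The median was 0.17, with rps-27 at 0.47 (camera adjusted p = 3.31e-05, and adjusted p = 0.718 with an estimated correlation). Across 12 basement membrane genes in footprints, 0 rose, 0 fell and 12 did not pass, or 0 rose and 7 fell adjusted over the list alone. The median was -0.60, with lam-2 at -0.96 and lam-3 at -1.74 (camera adjusted p = 8.83e-05, and adjusted p = 0.605 with an estimated correlation). The glucuronosyltransferase gene ugt-34 was among the lowest at -5.05 (SE 0.564). rRNA took 2.34% and 1.18% of the YFP-UTR footprint counts and 9.12% and 5.94% of the YFP-STOP counts. Of 6085 genes in footprints, 132 passed the threshold (edgeR quasi-likelihood), 13 of them higher and the others lower, against 51 in all by DESeq2, 385 with no filter and 283 with the replicate block. Without YFP-UTR replicate B there were 41, and without YFP-STOP replicate B 254. Translation efficiency of YFP was -0.69 (SE 0.110) and that of gcn-1 0.01 (SE 0.0944), which did not pass. The ER chaperone gene dnj-27, which overlaps other genes, stood at 3.91, with 451 and 10.1 CPM in the YFP-UTR footprints, and tmem-39 at 2.29 (SE 0.585). In translation efficiency 12 of 83 ribosomal protein genes rose and 0 fell, or 25 and 0 adjusted over the list alone. The median was 0.14, with rps-27 at 0.45 and rps-25 at 0.43 (camera adjusted p = 7.24e-04, and adjusted p = 0.601 with an estimated correlation). There 82 of 15072 genes were higher and 183 lower, 650 in all without YFP-UTR footprint replicate A and 97 without YFP-STOP footprint replicate A. Without the former, dnj-27 was -0.54.

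**Figure D5:**
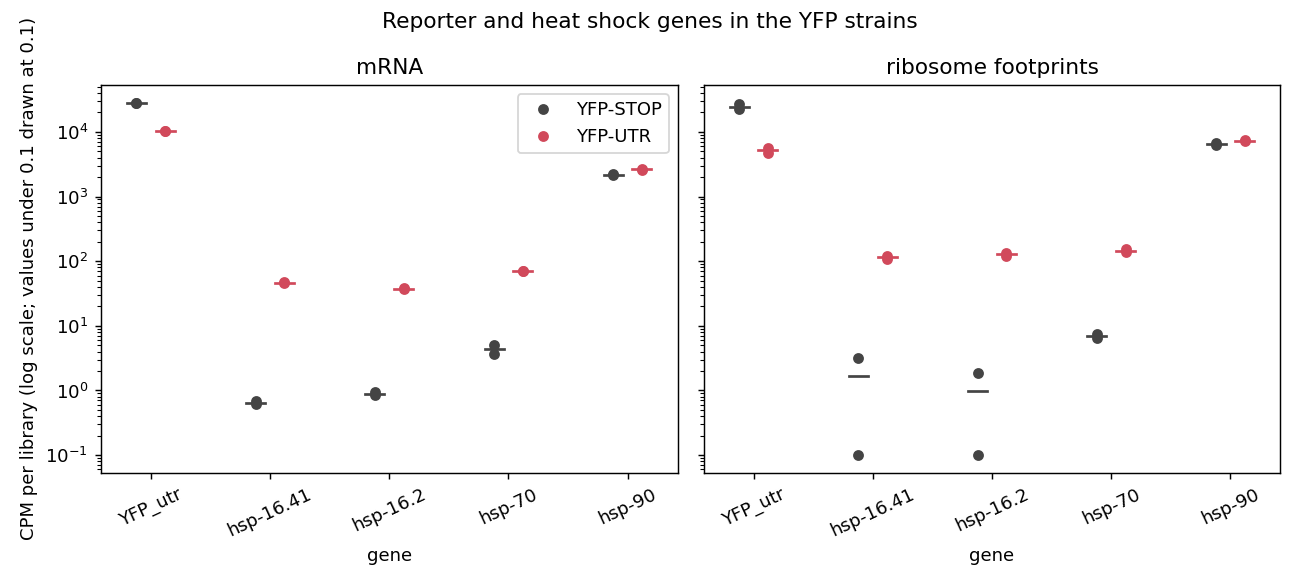
CPM (vertical axis, log scale) of the YFP reporter and 4 heat shock genes (horizontal axis) in mRNA (left) and footprints (right) of YFP-STOP (grey) and YFP-UTR (red), with a point per library and a bar at the mean of both. YFP mRNA was 10276 and 10352 CPM in YFP-UTR and 28417 and 27847 in YFP-STOP, while hsp-16.41 was 47.2 and 46.0 and 0.679 and 0.618.

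Over the worm comparisons 257 of 444 list tests passed by camera with its preset correlation, 139 up and 118 down. With an estimated correlation 3 passed, all in the footprint interaction of nc40 with age: cuticle collagens, aminoacyl-tRNA synthetases and detoxification enzymes.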

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

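The tests of trends with coding length and with abundance were chosen before their outcome was known, and the other tests of explanations in this part only after the result was seen. The following differences stood out because an effect differed between groups by a test of the interaction itself. IP enrichment in the worm differed between disomes and monosomes for 6670 genes, gcn-1 and the mitochondrially encoded mRNAs among them. In HEK293T cells it differed between treated and untreated cells for 3361 genes. The nc40 effect differed between day 6 and day 0 for 5948 genes in mRNA. In footprints it differed for 7395 genes, cuticle collagens among them.

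In the worm monosome IP mitochondrially encoded mRNAs (median 4.99) and small noncoding RNAs were above input. Whole mitochondrial ribosomes carried through the IP stay open. The 2 mitochondrial rRNAs had a median of -0.83 (-1.01 and -0.64, largest SE 0.226), which cannot decide this. All rRNA took a smaller share of the IP counts (4.29% and 2.16%) than of the input counts (11.4% and 9.63%). Counts of rRNA therefore need not follow the ribosomes pulled down. Unequal depth is argued against, since with every library thinned to 5604819 counts the mitochondrial mRNAs stayed 4.72 above all genes. RNA fragments other than ribosome footprints, held back in the IP, stay open. That 258 of 280 snoRNAs, snRNAs and tRNAs were higher (median 3.76) only restates the pattern. In the disome IP snoRNAs had a median of 2.31 (86 of 117 higher) and tRNAs of -1.69 (73 of 157 lower). Binding of GCN-1 to these RNAs in the animal is the biological alternative and was not tested.

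Enrichment in both IPs rose with coding length. With this removed, 7 of 8 lists called on fold changes kept call and direction in monosomes (87.5%) and 8 of 10 in disomes (80%). For these lists that argues against length as the whole cause. The ER response, mRNA decay and vitellogenin lists were not among them. In disomes transporters kept their call, but their median went from 0.90 (quartiles 0.15 and 1.77) to 0.29 (-0.28 and 1.19). Basement membrane genes lost theirs there, from 1.59 (0.78 and 1.87) to -0.01 (-0.34 and 0.21). Immune genes did too, from -0.62 (-1.41 and 0.25) to -0.58 (-1.13 and 0.21). Heat shock genes in monosomes, from -0.52 (-0.73 and -0.41) to -0.77 (-0.79 and -0.37), narrowly missed the threshold (adjusted p = 0.0541). With the trend on abundance removed, 8 of 10 (80%) kept theirs in disomes, not ribosomal protein genes, which went from -1.10 (quartiles -1.46 and -0.64) to -0.42 (-0.74 and 0.01), nor translation factors, from -0.89 (quartiles -1.16 and -0.20) to -0.58 (-1.11 and 0.04). In monosomes 2 of 8 (25%) did, mitochondrial mRNAs and chemoreceptors, and ribosomal protein genes went from -0.49 (quartiles -0.68 and -0.36) to 0.01 (-0.16 and 0.13) and proteasome genes from -0.48 (quartiles -0.54 and -0.41) to -0.18 (-0.27 and -0.08), so that the fall of the lists that lost their call cannot be told apart from a trend with abundance, since 25% met neither bound set beforehand, heat shock genes keeping most of theirs (from -0.52 (quartiles -0.73 and -0.41) to -0.37 (-0.61 and -0.07), adjusted p = 0.336). Preference of GCN-1 for ribosomes on long mRNAs and RNA other than footprints in the IP stay open and were not tested. Monosome enrichment ran opposite to occupancy for 3917 of 4457 shared calls (covariances -0.49 and -0.48 with different input replicates). Of 421 pseudogenes in monosomes 256 rose and 10 fell, and of 483 in disomes 248 and 5.

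The day 6 nc40 differences ran opposite to N2 ageing. Noise private to a single N2 library is argued against as the whole cause. With a different replicate in each comparison the higher covariance was -0.52 in mRNA and -0.82 in footprints. A deviation of both replicates stays open. Day 0 animals or RNA mixed into the nc40 libraries at one share are argued against as the whole cause. The share needed per gene ran from 4.45% to 76.8% (5th to 95th percentile of 23 genes, ratio 17.3, median 18.8%) in mRNA. In footprints it ran from 1.68% to 61.9% (54 genes, ratio 36.9, median 13.4%). Mixing beside a genotype difference stays open. A slower course of adult change in the gcn-1 mutant may account for the pattern, and so could a different time of harvest or, in footprints alone, for which the labels list FUdR, a different response to it. None of these was tested.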

How the results depend on the processing

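All settings with replicate A of the treated HEK293T input, and those limited to genes under 500 counts, were chosen only after the data were seen. Counts of genes past the threshold stayed within 1.5 times the reported count with RLE factors in all 21 comparisons. DESeq2 gave 3819 for the monosome IP, 4324 for the untreated HEK293T IP, 4850 for the treated IP, 1719 for their difference, 2469 for treated against untreated input, 1744 for nc40 at day 0 in mRNA, 3390 in footprints, 1020 in translation efficiency, 1360 for YFP-UTR in mRNA and 51 in footprints. With no filter beyond 1 count the treated HEK293T IP had 0 genes past the threshold by edgeR (10029 at an unadjusted p under 0.05, and 4850 by DESeq2 on filtered genes) with 1 residual degree of freedom, and YFP footprints had 385. The replicate block gave 283 in YFP footprints. With replicate A of the treated input as deposited, the treated IP had 4694, its difference from the untreated one 0 by edgeR (2964 at an unadjusted p under 0.05, 1719 by DESeq2 without that library) and input 2188. Over genes under 500 counts in replicate B these were 5955, 1420 and 3610, or 5390, 986 and 2169 without that library and 5985, 1478 and 3721 with it and the replicate block, where fewer genes were tested. For the other settings the cause was not tested. With 1 library left out, its partner was assumed to vary like the other groups, and counts ran as follows: monosome IP 3641 to 6413, disome IP 7327 to 9083, disome against monosome 5289 to 6781, FLAG strain occupancy 9893 to 10623, untreated HEK293T IP 4199 to 7510, treated against untreated IP 1824 to 4044, nc40 day 0 mRNA 2415 to 3056, footprints 3638 to 4686, translation efficiency 990 to 1631, day 6 mRNA 9317 to 9935, footprints 8786 to 9502, translation efficiency 5087 to 5772, day 6 against day 0 mRNA 4628 to 5843, footprints 6026 to 6692, N2 ageing mRNA 13135 to 14063, footprints 12260 to 12959, YFP mRNA 1734 to 2247, footprints 41 to 254, translation efficiency 97 to 650. Counts moved over 1.5 times without the libraries named in the Results for the monosome and untreated HEK293T IPs. So did treated against untreated IP and day 0 translation efficiency. For YFP it held without the libraries named in the Results. The cause was not tested. The treated HEK293T IP and input were not run this way, because no residual degree of freedom would remain. Half-lives were longer in GCN1 for 87% of genes within 0.5 to 24, 94.5% of the 6151 with the better fits by R squared and, by construction, 50% when centred. Of 257 list calls 3 kept call and direction with an estimated correlation and 251 with the replicate block. Of 913 named gene values 833 kept direction and side of the threshold in every setting run. dnj-27 in YFP translation efficiency ran from -0.54 to 7.22 with 1 library left out, the lowest without YFP-UTR footprint replicate A. gcn-1 changed sign with 1 library left out only where it had not passed: it ran from -0.19 to 0.015 in day 0 translation efficiency (highest without nc40 mRNA replicate B), from -0.25 to 0.0038 in day 6 mRNA (highest without N2 replicate B), from -0.081 to 0.18 in day 6 against day 0 mRNA (below 0 without N2 day 6 or nc40 day 0 replicate A), from -0.12 to 0.083 in YFP footprints (above 0 without YFP-UTR replicate A or YFP-STOP replicate B, and 0.087 with no filter) and from -0.036 to 0.23 in YFP translation efficiency (below 0 without YFP-STOP footprint replicate A or mRNA replicate B). The YFP footprint libraries, at 653142 counts and up, limit what can be seen: 6085 genes could be tested there against 14321 in mRNA.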

Other observations

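The test of microRNA reads in this part was chosen before its result was seen, and the tests of nascent chains and of warmer handling only after. Genes of amino acid synthesis and of ATF-4, a factor downstream of GCN2, were mostly higher in mRNA of nc40 at day 6 and lower in N2 mRNA with age. Of 14 such genes in mRNA, 10 rose, 3 fell and 1 did not pass, or 10 rose and 3 fell adjusted over the list alone. The median was 0.60, with cth-1 at 1.74 and gln-3 at 1.13 (camera adjusted p = 0.00796, and adjusted p = 0.381 with an estimated correlation). Among 14 such genes in N2 mRNA with age, 2 rose, 12 fell and 0 did not pass, or 2 rose and 12 fell adjusted over the list alone. The median was -0.74, with gln-5 at -2.07 and pyc-1 at -2.05 (camera adjusted p = 0.00281, and adjusted p = 0.273 with an estimated correlation). At day 0 in nc40 mRNA 7 of 14 were higher and 2 lower, with a median of 0.17, and the list did not pass (camera adjusted p = 0.0508). cth-1 and gln-3 encode enzymes of cysteine and glutamine synthesis. Of 39 translation factor genes in the monosome IP, 2 rose, 30 fell and 7 did not pass, or 2 rose and 32 fell adjusted over the list alone. The median was -0.39, with eif-6 at -1.01 and eef-1B.2 at -0.86 (camera adjusted p = 7.88e-08, and adjusted p = 0.338 with an estimated correlation). Among 39 such genes in the disome IP, 5 rose, 27 fell and 7 did not pass, or 5 rose and 28 fell adjusted over the list alone. The median was -0.89, with eef-2 at -1.31 and eef-1A.1 at -1.44 (camera adjusted p = 9.15e-05, and adjusted p = 0.178 with an estimated correlation). Of 15 heat shock genes in the monosome IP, 0 rose, 8 fell and 7 did not pass, or 0 rose and 9 fell adjusted over the list alone. The median was -0.52, with hsp-43 at -0.79 (camera adjusted p = 4.80e-04, and adjusted p = 0.345 with an estimated correlation). Among 15 such genes in the disome IP, 0 rose, 11 fell and 4 did not pass, or 0 rose and 11 fell adjusted over the list alone. The median was -1.35, with hsp-90 at -1.64 and hsp-1 at -1.35 (camera adjusted p = 3.37e-04, and adjusted p = 0.178 with an estimated correlation).

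With age in N2 footprints, neuropeptide and cuticlin genes were among those higher. Of 54 neuronal genes, 46 rose, 3 fell and 5 did not pass, or 46 rose and 3 fell adjusted over the list alone. The median was 1.35, with flp-5 at 4.01 and flp-13 at 3.40 (camera adjusted p = 2.49e-06, and adjusted p = 0.316 with an estimated correlation). Among 32 cuticlin and related genes, 21 rose, 1 fell and 10 did not pass, or 21 rose and 1 fell adjusted over the list alone. The median was 1.44, with cutl-16 at 2.53 and cut-5 at 4.11 (camera adjusted p = 3.75e-04, and adjusted p = 0.468 with an estimated correlation). Across 41 histone genes in the nc40 effect at day 6 against day 0 in footprints, 1 rose, 26 fell and 14 did not pass, or 1 rose and 26 fell adjusted over the list alone. The median was -0.94, with his-62 at -1.35 and his-2 at -1.28 (camera adjusted p = 1.23e-05, and adjusted p = 0.271 with an estimated correlation). Of the genes with far more footprints in nc40 at day 6, cdr-3 had 79.2 and 84.0 CPM in nc40 against 0.131 and 0.189 in N2, gskl-2 173 and 201 against 1.17 and 1.05 and oac-32 762 and 708 against 4.54 and 5.48.

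The rise of gcn-1 in the monosome IP may come from ribosomes that were making the tagged protein and were held by the nascent chain. Capture of such chains on single and collided ribosomes alike is argued against by the disome IP, where gcn-1 stood at -0.065 (SE 0.0802). Reads of the 4 microRNAs inside the gene are argued against too, since they had 0.371% of its CPM in the IP. Among 637 nuclear coding genes with a mean log2 CPM of 8 or more, 1, gcn-1 itself, reached its fold change, and the 99th percentile was 0.63. Capture limited to single ribosomes, or lost with the way disomes were prepared, stays open and was not tested.

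The rise of hsp-16.2, hsp-16.41 and hsp-70 in the YFP-UTR strain could, as a hypothesis, be a stress response to the reporter. Lowering the reporter by RNAi in that strain, with these mRNAs measured, would test it. Reads shared between hsp-16 copies stay open. Warmer handling of those cultures cannot be told apart from the strain, because no culture held both strains: the other 12 heat shock genes had a median of 0.10.

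In HEK293T cells IP enrichment had a Spearman's rho with the length given in the half-life tables of 0.0188 untreated (8468 genes) and 0.0931 treated (8798). Median log2 half-life ratios within 0.5 to 24 were 0.60 in genes enriched in the untreated IP, at percentile 98.3 of random lists. Depleted genes had 0.55, at percentile 0.02. For the better fits by R squared they were 0.58, at 99.6, and 0.52, below every random list.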
